A study of Arabidopsis thaliana with 10 samples.

How the data were processed

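RNA from *Arabidopsis thaliana* was measured on 10 Affymetrix ATH1 arrays, which carry 22810 probe sets, 64 of them controls. Plants were 21 days old, and were either wild type (Col-0) or Ri17, a line in which RNA interference targets *JAV1*. Each genotype had 1 array for each of 5 conditions: untreated, 100 µM methyl jasmonate (MeJA) for 1 h or 4 h, and 30 min or 60 min after wounding. Wounding meant crushing 4 rosette leaves with forceps, which damaged about 30% of each leaf. No combination of genotype and condition was repeated, and both kinds of treatment share the same pair of untreated arrays.

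The authors made signal intensities with GCOS, named in the submitters' processing notes without a version, and scaled them so that the mean of each array, trimmed by 2% at each end, was 500.1. The deposited intensities are linear, and those in the comparison tables were identical to those in the series table (largest difference 0.0). The deposited log2 ratios set the Ri17 array over the Col-0 array of the same condition. The deposited p-value of the change between both arrays comes from the probe pairs and lies near 0 for an increase and near 1 for a decrease. Other deposited columns hold detection calls (Present, Marginal, Absent) and change calls, per the file headers.

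Signals below 37.7, the 75th percentile of signals called Absent, were set to that floor, and log2 values were taken. Probe sets called Present on at least 2 arrays were kept, 15382 in all. A probe set was given a gene name where the annotation table supplied for it listed 1 gene. That held for 13513 probe sets, 13436 of which matched the TAIR10.1 gene table. The table listed several genes for 503 probe sets and none for 8730, and a further 63 probe sets were named from their deposited descriptions. A gene with several probe sets is represented by the one with the highest mean log2 signal. Of 308 genes in 25 fixed lists, 118 had a named probe set. *JAV1* and the *JAZ* repressors had none and were not analysed here.

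Treatments and genotypes were compared with limma 3.58.1 in R 4.3.3, with genotype and condition as additive terms (lmFit, eBayes, 4 residual degrees of freedom), two-sided, and with Benjamini-Hochberg adjustment at a threshold of 0.05. Because no group had a repeat, the spread in this model holds array noise together with any real difference between the genotypes in their response. Comparisons of single arrays carry no test. They count probe sets that differ by at least 1 on the log2 scale with a Present call on the higher array. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for these counts and for the plots.

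Lists with at least 5 kept members were tested with camera (correlation preset to 0.01), adjusted over lists and 5 contrasts, with an estimated correlation, fry and quantile-normalised values as alternatives. In single-array comparisons, the median of a list was set against 10000 random lists matched on expression in 10 bins. These lists were drawn gene by gene, so their percentiles do not allow for genes that move together. A further 27 groups, each defined by a word in the deposited descriptions, were fixed after the descriptions had been read and before differences between arrays were computed.

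The comparisons, the tests, the gene lists and the rule for named genes were set before the data were examined. The rule took up to 4 members per list and contrast by size of change. It also took the 10 highest and 10 lowest genes past the threshold in each contrast with the same sign in every pair of arrays. In single-array comparisons it took the 5 highest and 5 lowest genes above the floor. Contrasts between times and between wounding and MeJA were added after the data had been seen.

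The same steps were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. Changed genes were drawn among those with higher mean signal, and noise was independent between genes. Genotype changes were equal in every condition, and treatment changes equal in both genotypes. For genotype they recovered 64 and 95 of these, with 9 false calls among 168. For the treatments they recovered 11 to 25 of the genes changed by 1 and 75 to 85 of those changed by 2. Alternatives covered 2 other scalings, the floor, the detection filter, the variance model, leaving out each array, and subsets of conditions. Between 56.8% and 60.9% of probe sets were called Present on each array, and the number of arrays limits the precision.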

Results

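Transcript levels were compared between wild-type *Arabidopsis* (Col-0) and the *JAV1* RNA interference line Ri17, untreated and after MeJA or wounding, on 10 arrays with 1 array per genotype and condition. Median signal ran from 121.5 to 133.4 across the arrays, and between 12912 and 13846 probe sets were called Present on each. Treatment effects are log2 differences ± standard error from limma, each the mean of 2 differences between single arrays, 1 per genotype. Where a value is given as "at least", 1 or both arrays on its lower side lay at or under the floor, so that it is a bound and carries no error. A value called floored was fitted without 1 array and rests in part on arrays under the floor. Values for Ri17 against Col-0 within a condition are differences between 2 single arrays and carry no error. Expression of *JAV1* itself was not analysed here, since no probe set was named for it. The deposited design speaks of seedlings in MS medium for MeJA and of harvested leaves for wounding and for untreated plants, so a difference in tissue between MeJA and untreated arrays is possible and was not tested.

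**Figure D1:**
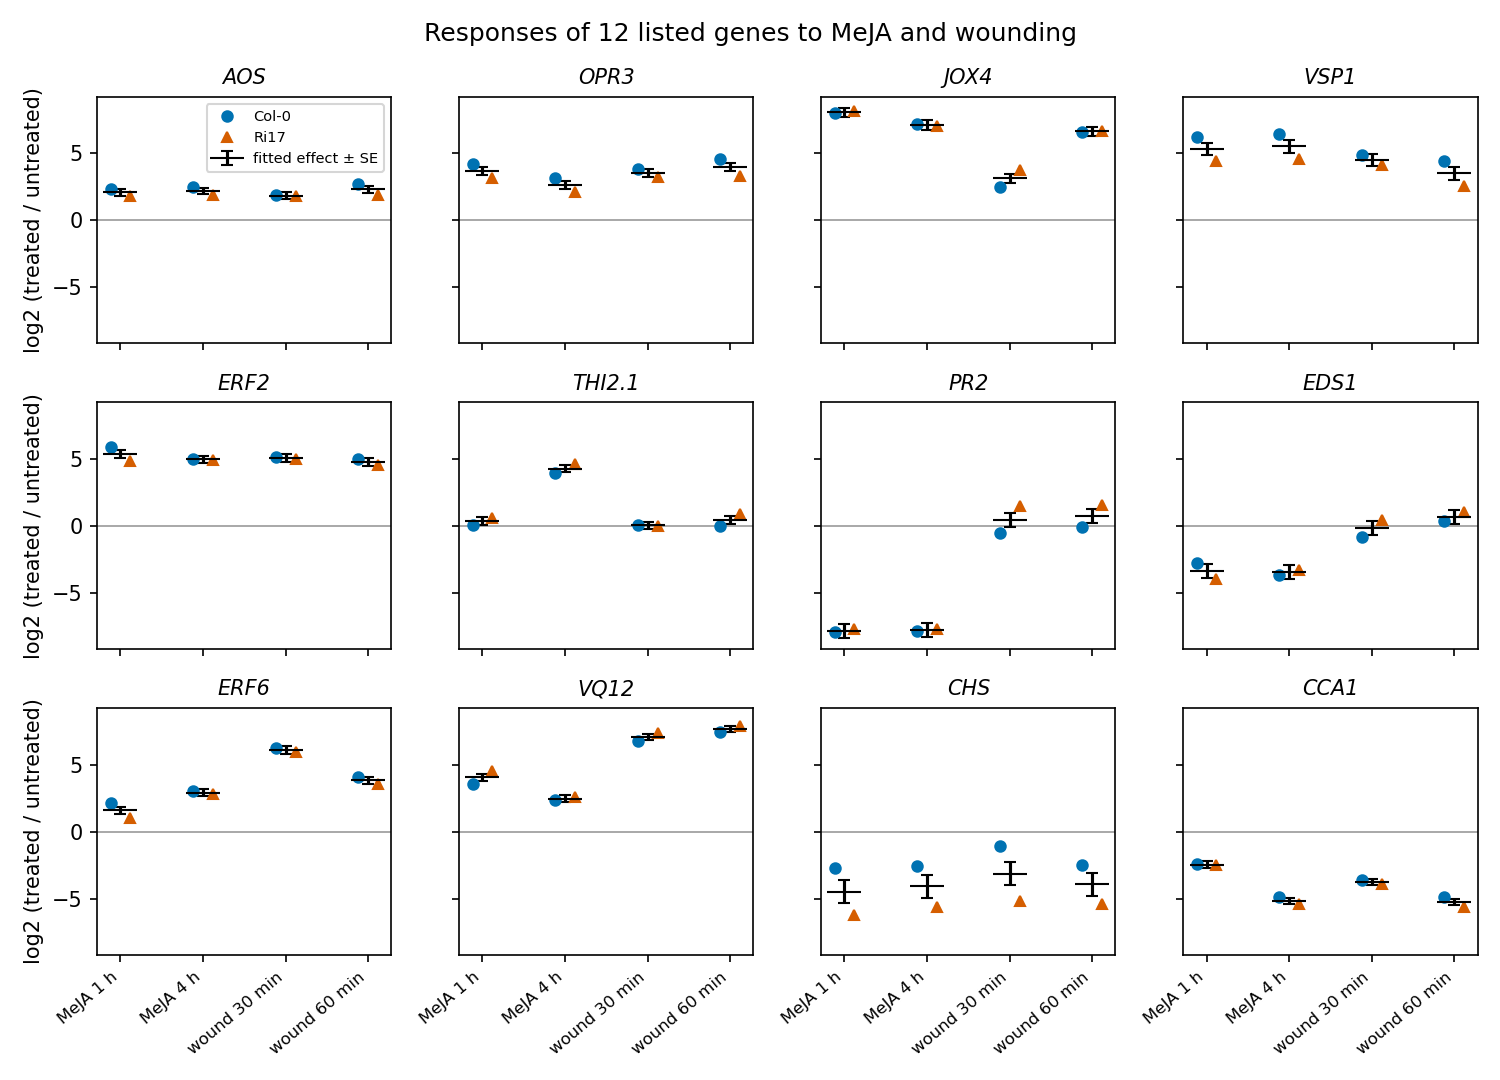
Each panel plots the log2 ratio of treated to untreated signal (vertical axis) for 1 of 12 listed genes at 4 treatments (horizontal axis), with circles for Col-0, triangles for Ri17 (1 array each) and bars for the fitted effect ± standard error. *JOX4* and *ERF2* lie above 0 at every treatment, and *PR2* lies far below 0 under MeJA alone, where 1 of 2 arrays at each time was under the floor, so that its fitted values of -7.81 and -7.74 are bounds.

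MeJA for 1 h against no treatment addressed the early response to the treatment as a whole. No array held plants given the medium without MeJA, so effects of medium or handling cannot be told apart from those of the hormone. That limit applies to every MeJA effect given here, including those of touch and heat shock genes. Genes of jasmonate synthesis rose, among them *OPR3*, which reduces the precursor OPDA, by 3.69 ± 0.31 (adjusted p = 2.84e-04), and *AOS*, the allene oxide synthase, by 2.09 ± 0.24 (adjusted p = 9.63e-04). Genes of jasmonate oxidation rose as well, *JOX2* by 5.21 ± 0.20 and *JOX4* by at least 8.05 (adjusted p = 6.51e-05, 1 of 2 untreated arrays under the floor). The wound marker *VSP1* rose by 5.32 ± 0.47. *PR2*, a glucanase gene of salicylate defence, fell by at least 7.81 (adjusted p = 1.35e-04, 1 of 2 MeJA arrays under the floor), and *EDS1*, a regulator of that defence, fell by 3.37 ± 0.51. All of these went the same way in both genotypes.

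At 1 h of MeJA, 4 of the 5 kept jasmonate synthesis genes rose (4 when adjusted over the list alone), with a list adjusted p of 7.22e-04 in camera. The other, *AIM1*, measured 0.40. In salicylate defence 3 of 5 genes fell (4 adjusted over the list alone), with a list adjusted p of 0.0175. In the anthocyanin list 6 of 7 fell (7 adjusted over the list alone, list adjusted p = 1.65e-04), including *TT5*, a chalcone isomerase, at -2.64 and *UGT78D2*, a flavonoid glucosyltransferase, at -2.45. Of these 6, the call for *CHS* was lost without the Ri17 array at 1 h of MeJA (-3.97, adjusted p = 0.0719), and that for *UF3GT* without any of 6 single arrays (a floored -1.66 without the untreated Col-0 array). Of 5 genes of the abscisic acid and cold response 4 rose, *RD29B* by at least 3.29 (both untreated arrays under the floor), and *ABI1*, a phosphatase that restrains abscisic acid signalling, fell by 0.84 (4 and 1 adjusted over the list alone, list adjusted p = 0.0302). The call for *ABI1* was lost without any of 5 single arrays, among them the untreated Col-0 array (-0.53, adjusted p = 0.116), and that for *COR47* without the Col-0 array at 1 h of MeJA (0.74) or the untreated Col-0 array (0.88). With an estimated correlation these 4 list calls were lost (adjusted p = 0.226 for jasmonate synthesis, anthocyanin and abscisic acid, adjusted p = 0.325 for salicylate defence). The heat shock list, too small for a list test, had 4 of 4 genes higher, with *HSP70-4* up by 3.55 ± 0.57. Without the Col-0 array at 1 h of MeJA the calls for *HSP101* (2.16) and *HSP17.6II* (a floored 1.47) were lost, and without the untreated Col-0 array that for *HSP101* (2.24). Among the other leading genes were those for cell wall enzymes, *TCH4* (6.66 ± 0.34) and *XTH18* (at least 6.35, 1 untreated array under the floor), the methyltransferase gene *BSMT1* (at least 6.72, both untreated arrays under the floor) and *EXO* (6.85 ± 0.29). The cytochrome P450 gene *CYP71B23* fell by at least 6.22, with both MeJA arrays under the floor.

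The remaining lists at 1 h of MeJA were mixed. *ERF1A* and *ERF2*, genes of ethylene response factors, rose by 5.07 and 5.36, while *PR4*, a chitin-binding protein gene of the same list, fell by 3.31, so that the ERF branch list did not pass (list adjusted p = 0.444, 2 higher and 2 lower of 7, 3 higher and 2 lower adjusted over the list alone). Among 12 early wound and touch genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.176): *WRKY53* fell by at least 4.08 (1 MeJA array under the floor) and *ZAT10*, a zinc finger repressor, rose by 2.19. *COI1*, the jasmonate receptor gene, fell by 1.43, and *MYC4* by 1.76. *MYB28*, a regulator of aliphatic glucosinolates, fell by 1.94. The call for *MYC4* was lost without the Col-0 array at 1 h of MeJA (-1.59). That for *PDF1.2A* in the ERF branch was lost without any of 7 single arrays (-0.83 without the untreated Ri17 array). That for *ERF5* in the early wound list was lost without any of 3 (1.17 without the untreated Ri17 array).

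In all, 2413 probe sets were higher and 2427 lower at 1 h of MeJA among 15382 tested. Without the Ri17 array at 1 h of MeJA the total was 2467, and without the Col-0 array 2494. Bacterial controls set the 4 MeJA arrays apart from the 6 others: for 23 of 45 control probe sets the 2 sets of arrays did not overlap, where chance gives 0.952% for each. Several probe sets measure the same transcript and are not independent. Of 27 poly-A controls, which are added to the RNA, 17 were separate, with a median of 0.53 for MeJA minus the others, and 3, for trp, lay at or near the floor. Of 18 hybridization controls 6 were separate, with a median of -0.38.

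MeJA for 4 h addressed the later response, again without an array for the medium alone. *JOX4* stood at least 7.10 above the untreated level (adjusted p = 3.27e-05, 1 untreated array under the floor), and *VSP1* 5.52 ± 0.47. *THI2.1*, an antifungal thionin gene, rose by at least 4.29 (adjusted p = 8.06e-05, both untreated arrays under the floor) and did not pass at 1 h, a difference between times of 3.93 (adjusted p = 0.0013). The tryptophan synthesis genes *TSA1*, *TSB2* and *IGPS* rose by 1.86, 1.64 and 1.54, all 3 with a probe set among 8 in the list. *PR2* was again low, by at least 7.74, with 1 MeJA array under the floor.

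At 4 h of MeJA jasmonate synthesis had 4 of 5 genes higher (5 adjusted over the list alone, list adjusted p = 0.00239) and the anthocyanin list 6 of 7 lower (7 adjusted over the list alone, list adjusted p = 1.65e-04). Among these 6, the call for *CHS* was lost without the Col-0 (-4.29) or the Ri17 array (-3.84) of that time, and that for *UF3GT* without any of 6 single arrays (a floored -1.66 without the untreated Col-0 array). The ERF branch list had 3 of 7 genes higher (3 adjusted over the list alone, list adjusted p = 0.032), *ERF1A* by 5.46. All 3 list calls were lost with an estimated correlation (adjusted p = 0.226). Salicylate defence did not pass (list adjusted p = 0.0569): 3 of 5 genes fell, *SAG101* by 2.16, and *GRX480*, a glutaredoxin gene, rose by 1.66 (4 lower and 1 higher adjusted over the list alone), a call lost without the Col-0 array at 4 h of MeJA (1.18, adjusted p = 0.192) or the untreated Col-0 array (1.06, adjusted p = 0.167). *CCA1*, a morning gene of the circadian clock, fell by 5.12 ± 0.23. *GH3.3*, which conjugates auxin to amino acids, rose by at least 4.64 (both untreated arrays under the floor), while *IAA3*, an auxin repressor gene, fell by 3.06. The leading genes also included the glucosyltransferase gene *UGT76E12* (at least 6.38, 1 untreated array under the floor) and the glutaredoxin gene *AT1G06830* (-6.71 ± 0.33).

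At 4 h of MeJA 2888 probe sets were higher and 2881 lower, and the total was 3149 without the Col-0 array of that time and 3459 without the Ri17 array. Compared directly, in a contrast added after the data were seen and within the MeJA arrays alone, 1029 probe sets were higher at 4 h than at 1 h and 1220 lower. *UGT73C1* was higher at 4 h by 3.74 and *UGT76B1* by at least 4.17 (both arrays at 1 h under the floor), while the wall enzyme genes *XTH19* and *XTH33* differed by -3.42 and -3.41.

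Wounding for 30 min addressed the first response to leaf damage. Transcription factor genes of the early wound list rose sharply, with *ZAT10* up by 4.76 ± 0.34, *ERF6* by at least 6.09 (adjusted p = 5.17e-05, both untreated arrays under the floor) and the cold regulator gene *CBF2* by at least 4.19 (1 untreated array under the floor). *CML38*, a calmodulin-like gene, rose by 7.10 ± 0.19 (adjusted p = 1.25e-05) and *VQ12*, of the VQ motif family to which *JAV1* belongs, by at least 7.08 (1 untreated array under the floor). *OPR3* rose by 3.53 ± 0.31, and *ORA47*, an AP2 factor gene, by 5.79 ± 0.22. *F3H*, a flavanone hydroxylase gene, fell by 5.04 ± 0.40. These genes moved the same way in both genotypes.

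At 30 min all 12 early wound and touch genes rose (12 adjusted over the list alone, list adjusted p = 1.32e-10). Of these 12, 5 lost their call without single arrays: *WRKY53* without any of 7 (1.81 without the untreated Ri17 array), *WRKY6* without any of 8 (0.70 without the same array), *CBF1* without any of 3 (a floored 2.07 without the Col-0 array at 30 min), *MPK3* without the Col-0 (1.76) or Ri17 array (1.49) of that time, and *TCH2* without that Ri17 array (1.41). All 5 jasmonate synthesis genes rose (5 adjusted over the list alone, list adjusted p = 5.76e-05), and 3 of 7 in the ERF branch did (3 adjusted over the list alone, list adjusted p = 0.0135). Among jasmonate synthesis genes the calls for *LOX2* (0.98 without the untreated Col-0 array) and *AIM1* (0.71 without the untreated Ri17 array) were each lost without any of 3 arrays. In the anthocyanin list 5 of 7 fell (5 adjusted over the list alone, list adjusted p = 1.65e-04), with the call for *CHS* lost without any of 9 single arrays (-1.40 without the untreated Ri17 array). With an estimated correlation all 4 list calls were lost (adjusted p = 0.226). In salicylate defence 1 of 5 rose, *GRX480* by 4.23 ± 0.46, and *PR2* measured 0.48 ± 0.52 (1 adjusted over the list alone, list adjusted p = 0.131). *JOX4* rose by at least 3.14 (1 untreated array under the floor), and *JMT*, which makes MeJA, fell by 2.33 ± 0.32. *MYC4* fell by 3.39 and *CCA1* by 3.74. *HYH*, a light-signalling factor gene, fell by 4.41 ± 0.28.

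At 30 min of wounding 1482 probe sets were higher and 1616 lower. The total was 1452 without the Ri17 array of that time, 1553 without the Col-0 array, and 1467 in a fit on wounded and untreated arrays alone, which was added after the data were seen.

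Wounding for 60 min showed how this response went on. *CML38* stood 7.11 ± 0.19 above the untreated level (adjusted p = 1.25e-05), *VQ12* at least 7.68 and *JOX4* at least 6.64, each of these 2 with 1 untreated array under the floor. In a contrast added after the data were seen, *UGT76E12* was higher at 60 than at 30 min by at least 5.19 (adjusted p = 0.0093) and *BSMT1* by at least 3.27 (adjusted p = 0.0104), each with 1 array at 30 min under the floor, and *ERF6* was lower, at -2.24 (adjusted p = 0.0124). The dehydrin gene *LTI30* rose by 3.77 ± 0.37 and *COR15A*, a cold-response gene, by 3.94 ± 0.45. *TSB2* and *TSA1* rose by 1.72 and 1.52. *CCA1* fell by 5.25 ± 0.23, and the evening clock genes *TOC1* and *GI* rose by 2.52 and 2.02.

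At 60 min 9 of 12 early wound genes rose (11 adjusted over the list alone, list adjusted p = 4.25e-08), all 5 of jasmonate synthesis (5 adjusted over the list alone, list adjusted p = 8.29e-05), 3 of 7 in the ERF branch (3 adjusted over the list alone, list adjusted p = 0.00239) and 4 of 5 of the abscisic acid and cold response (5 adjusted over the list alone, list adjusted p = 1.65e-04). In the anthocyanin list 5 of 7 fell (5 adjusted over the list alone, list adjusted p = 2.25e-04), *UGT75C1* by at least 3.71, with both wounded arrays under the floor. Calls were lost for *CBF1* in the early wound list without any of 7 single arrays (a floored 1.02 without the Ri17 array at 60 min), for *AIM1* without any of 7 (0.51 without the untreated Ri17 array) and for *CHS* without either array at 60 min (-4.07 and -3.77). With an estimated correlation these 5 calls were lost (adjusted p = 0.226). Salicylate defence passed as higher (list adjusted p = 0.0368, adjusted p = 0.362 with an estimated correlation), with 1 of 5 genes past the threshold, *GRX480* at 4.37 (2 adjusted over the list alone).

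At 60 min 1867 probe sets were higher and 2474 lower, and the median over all probe sets was -0.14. The total was 2781 without the Ri17 array of that time and 2628 in the added fit on wounded and untreated arrays alone. The reference gene *ACT2* fell by 1.04 ± 0.18. The reference list held 3 lower genes of 8 (4 adjusted over the list alone, list adjusted p = 0.0812). Calls there were lost for *TIP41L* under both other scalings (-0.59 and -0.56) and without any of 9 single arrays (-0.43 without the untreated Col-0 array), and for *ACT8* without the Ri17 array at 60 min (-0.70). At 30 min 2 of the 8 were lower (2 adjusted over the list alone, list adjusted p = 0.0591, adjusted p = 0.0452 after quantile normalisation), *ACT2* by 0.92 and *ACT8* by 0.67. At 4 h of MeJA 2 were lower (2 adjusted over the list alone, list adjusted p = 0.181), *GAPC2* by 1.05 and *ACT2* by 0.66, while at 1 h of MeJA none passed. These calls were lost for *ACT2* without any of 3 arrays at 30 min (-0.84 without the Ri17 array of that time) and any of 4 at 4 h (-0.56 without the Col-0 array of that time), for *ACT8* without any of 7 (-0.58 without the untreated Ri17 array), and for *GAPC2* without the Ri17 array at 4 h (-0.96).

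**Figure D2:**
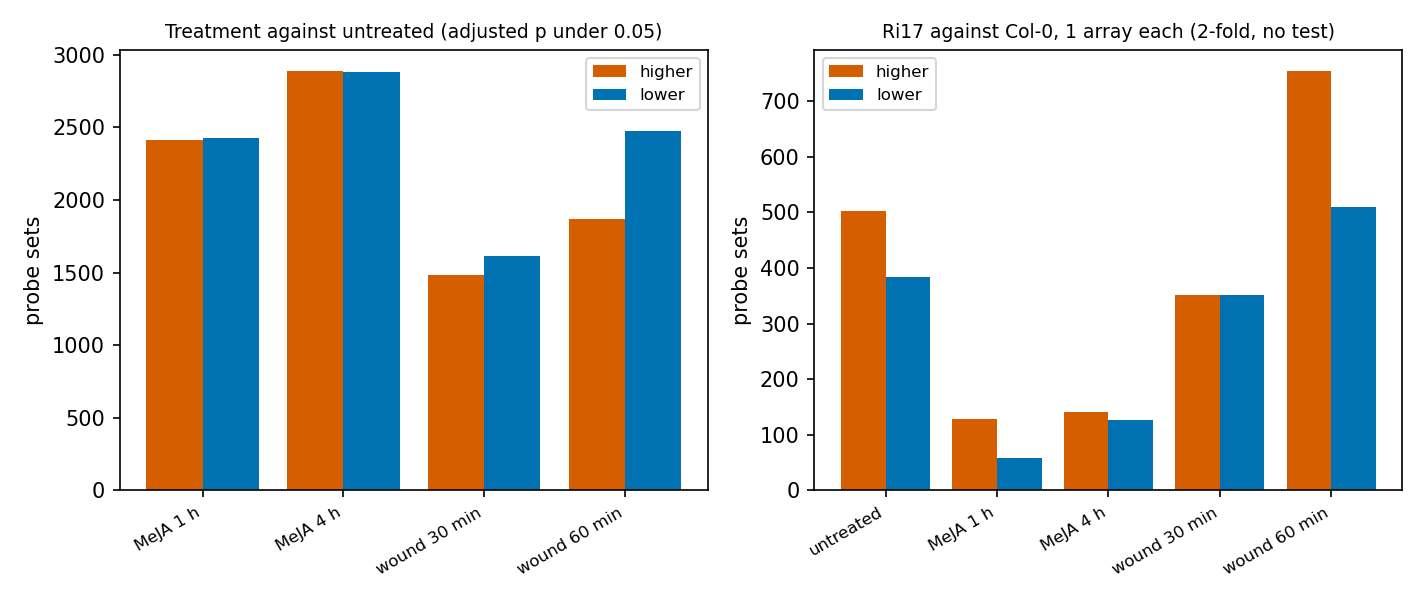
Left, probe sets past an adjusted p of 0.05 against untreated (vertical axis) at each of 4 treatments, higher and lower. Right, probe sets that differed 2-fold between Ri17 and Col-0 in each condition, from 1 array each and without a test: 1264 in all at 60 min of wounding and 187 at 1 h of MeJA.

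Smaller lists, with fewer than 5 kept genes and no list test, followed the treatments in part. Of 4 jasmonate catabolism genes 2 rose and 1 fell at 1 h of MeJA (3 and 1 adjusted over the list alone), 3 rose and 1 fell at 4 h, 2 rose and 1 fell at 30 min of wounding (3 and 1 adjusted over the list alone), and 3 rose at 60 min. The gene that fell was *JMT*, by 1.47 and 1.33 under MeJA. These calls were lost at 1 h without any of 3 arrays (-1.20 without the untreated Ri17 array) and at 4 h without the Ri17 array of that time (-0.76) or the untreated Ri17 array (-1.06). Of 3 genes of the MYC branch of wound defence 1 rose and 1 fell at 1 h of MeJA, 2 rose and 1 fell at 4 h, 1 rose and 1 fell at 30 min of wounding, and 1 rose at 60 min. The gene that fell was *PHO1;H10*, by 1.95 and 1.60 under MeJA and 1.80 at 30 min. These calls were lost at 1 h without the Ri17 array of that time (-1.65), at 4 h without the Col-0 array of that time (-1.40) or the untreated Col-0 array (-1.20), and at 30 min without any of 3 arrays (-1.40 without the untreated Col-0 array). Of the 4 heat shock genes none passed at 4 h of MeJA, 2 fell at 30 min of wounding and 2 rose at 60 min. At 30 min *HSP70-4* fell by 2.39 and *HSP101* by at least 2.24, calls each lost without any of 4 arrays (-1.96 for *HSP70-4* without the untreated Ri17 array, and a floored -1.87 for *HSP101* without the Ri17 array at 30 min). At 60 min *HSP17.6II* rose by at least 2.01, and *HSP17.6A* rose too, a call lost without any of 3 arrays (a floored 1.69 without the Ri17 array at 60 min). Of 4 VQ motif genes 1 rose and 1 fell at 1 h of MeJA, 2 rose at 4 h, and 3 rose at each wounding time. The call for *VQ32* was lost at 60 min without any of 8 single arrays (0.55 without the Ri17 array at 60 min) and at 30 min without the Col-0 array of that time (adjusted p = 0.0538). That for *VQ10* was lost at 1 h of MeJA without any of 3 (a floored -1.20 without the untreated Col-0 array) and at 4 h without any of 7 (0.74 without the untreated Ri17 array). Of 3 genes of jasmonate perception 2 fell at every treatment, *COI1* by 2.15 at 60 min of wounding. Its call at 30 min was lost without the Ri17 array of that time (-1.21), and that of *MYC4* at 1 h of MeJA without the Col-0 array (-1.59). Of 4 clock genes 1 fell at 1 h of MeJA (2 adjusted over the list alone), 1 rose and 1 fell at 4 h (2 and 1 adjusted over the list alone), and 2 rose and 1 fell at each wounding time (2 and 2 at 30 min adjusted over the list alone). The call for *TOC1* was lost at 30 min without any of 3 arrays (1.08 without the untreated Ri17 array) and that for *GI* without the Col-0 array at 30 min (1.42) and at 4 h of MeJA without the Ri17 array of that time (1.12) or the untreated Ri17 array (1.03).

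Of 6 auxin response genes 1 rose and 3 fell at 1 h of MeJA (1 and 3 adjusted over the list alone, list adjusted p = 0.181). The calls were lost for *GH3.5* without any of 5 single arrays (-0.68 without the Col-0 array at 1 h) and for *IAA3* without any of 3 (-0.60 without the Ri17 array at 1 h). At 4 h 1 rose and 3 fell again (1 and 3 adjusted over the list alone, list adjusted p = 0.343), at 30 min of wounding 1 fell (1 adjusted over the list alone, list adjusted p = 0.500), and at 60 min 1 rose and 2 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.672). The call for *IAA1* at 60 min was lost without any of 4 arrays (-0.57 without the untreated Ri17 array). The abscisic acid and cold list had 3 genes higher and 1 lower of 5 at 4 h of MeJA (3 and 1 adjusted over the list alone, list adjusted p = 0.389) and 3 higher at 30 min of wounding (3 adjusted over the list alone, list adjusted p = 0.0572). At 4 h calls were lost for *COR15A* without any of 9 arrays (0.56 without the untreated Col-0 array), *COR47* without any of 3 (-0.71 without the untreated Ri17 array) and *LTI30* without the Col-0 array of that time (1.83). At 30 min they were lost for *COR15A* without either array of that time (2.72 and 2.81), *COR47* without any of 3 (0.89 without the untreated Col-0 array) and *LTI30* without either untreated array (2.03 and 1.91). The early wound list had 5 genes higher and 2 lower of 12 at 4 h of MeJA (5 and 2 adjusted over the list alone, list adjusted p = 0.247), *TCH2* losing its call without any of 3 arrays (-0.95 without the untreated Col-0 array).

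MeJA and wounding share the untreated arrays, so likeness between them is partly built in. Of the probe sets past the threshold, 899 were higher and 1182 lower both at 1 h of MeJA and at 60 min of wounding, where independent lists would share 293 and 390. *JOX4*, *VSP1* and *ERF2* were higher in both, and *F3H* and *CCA1* lower. Another 231 went opposite ways. Across probe sets, which are not independent replicates, the effects correlated with r = 0.51 and a covariance of 0.65, against 0.50 and 0.06 in 100 simulations of unchanged groups with the same shared controls. Between Col-0 under MeJA and Ri17 after wounding, which share no array, r was 0.32, and in the reverse pairing 0.48.

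Ri17 against Col-0 over the 5 conditions addressed what the *JAV1* construct changed throughout. The salicylate synthesis gene *ICS1* measured 1.13 ± 0.37 in Ri17 against Col-0, the chaperone gene *HSP70-4* 1.13 ± 0.36 and the clock gene *CCA1* -0.52 ± 0.14, none of them past the threshold. With limma 0 of 15382 probe sets passed, 951 had an unadjusted p under 0.05, and the lowest adjusted p was 0.799. As a list, the ERF branch lay higher in Ri17 (list adjusted p = 2.25e-04, median 0.43, adjusted p = 0.226 with an estimated correlation), with 0 of 7 genes past the threshold and 1 when adjusted over the list alone. Salicylate defence did so too (list adjusted p = 0.0137, median 0.41, adjusted p = 0.316 with an estimated correlation), with 0 of 5 genes past it, also when adjusted over the list alone. Such averages over 5 conditions do not show a shift in each of them. In salicylate defence the medians were highest after wounding, as given below. *PR2*, *EDS1* and *GRX480* were lower in Ri17 at 1 h of MeJA, and *SAG101* and *ICS1* higher. Jasmonate synthesis measured a median of 0.08 (list adjusted p = 0.398), and the photosynthesis list -0.17 (list adjusted p = 0.0514).

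Within single conditions, Ri17 and Col-0 differed most before treatment and after wounding. The MeJA arrays, where they differed least, are also those that the bacterial controls set apart. A separate run, if there was one, cannot be told apart from the treatment here. Salicylate defence genes were higher on the wounded Ri17 arrays, by a median of 1.45 at 30 min and 0.90 at 60 min, above 100% and 99.9% of random lists. *ICS1* was higher by 1.82 and 2.64, and *PR2* by 1.53 and 1.21. The random lists took genes singly, so percentiles here and below describe these arrays and are not p-values. The early wound list was lower in untreated Ri17 (median -0.43 or lower, percentile 0.22, 4 of 12 genes under the floor on 1 or both arrays), with *TCH4* at -1.36, and higher at 60 min of wounding (median 0.64, percentile 100), with *WRKY53* at 2.31. Anthocyanin genes were lower in Ri17 at 30 min of wounding, 7 of 7 below Col-0, with a median of -1.01 or lower, since *UGT75C1*, which sets it, and *DFR* lay under the floor on the Ri17 array.

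**Figure D3:**
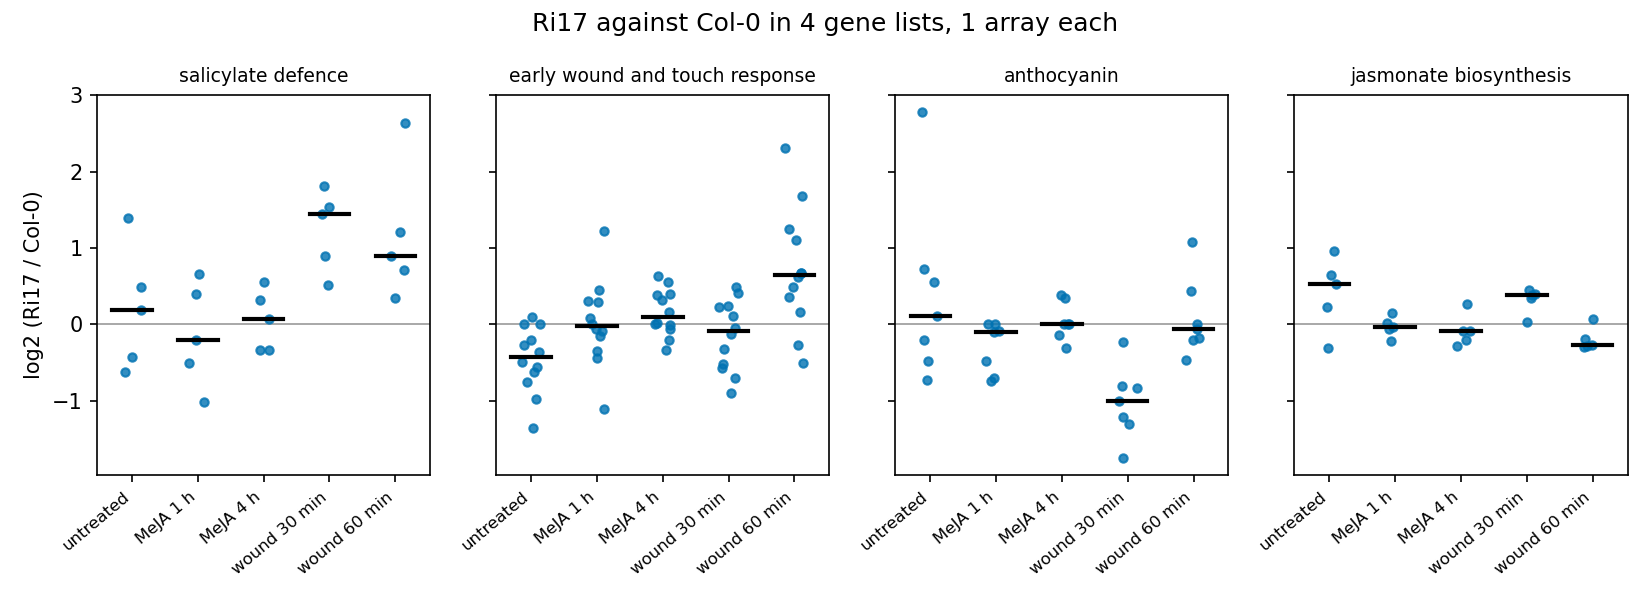
Log2 ratio of Ri17 to Col-0 signal (vertical axis) in 5 conditions (horizontal axis) for 4 gene lists. Points are genes, from 1 array per genotype, and bars are list medians: salicylate defence lies highest at 30 min of wounding, with a median of 1.45.

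By size alone, 503 probe sets were higher and 384 lower in untreated Ri17, 129 and 58 at 1 h of MeJA, 141 and 127 at 4 h, 351 and 352 at 30 min of wounding, and 754 and 510 at 60 min. After quantile normalisation the balance changed to 79 and 72 at 1 h of MeJA and to 452 and 300 at 30 min of wounding, so the balance at these times depended on the scaling. A double floor gave 53 and 28 at 1 h of MeJA and 77 and 62 at 4 h. At 30 min of wounding it gave 263 and 212. A Present call on both arrays gave 70 and 31 at 1 h of MeJA. At 30 min of wounding that rule gave 239 and 207, and at 60 min 488 and 406. A change call of the authors in the same direction was found for 65 of the 129 and 28 of the 58 at 1 h of MeJA, and for 85 of the 141 and 75 of the 127 at 4 h. In the untreated pair *AT1G60590*, a putative polygalacturonase gene, was higher in Ri17 by 4.11 and *CHIL*, a chalcone isomerase-like gene, by 3.07, while *AT4G12490*, which encodes a pEARLI1-like protein, differed by -4.15. *AT4G12490* also stood lower in Ri17 at 30 and 60 min of wounding, at -3.78 and -2.42. At 60 min *AT5G20790* was higher by 5.44 and *AT1G72890*, a putative resistance gene, by 3.28. *CYP71B22* was higher at both MeJA times, by 1.62 and 1.81, where the deposited ratios from the probe pairs were 0.4 and 1.9, so its size at 1 h depended on the measure. Jasmonate synthesis showed medians of 0.53 untreated, -0.04 and -0.09 under MeJA, 0.38 at 30 min and -0.28 at 60 min of wounding, the last turning to 0.03 after quantile normalisation. With 1 array each, none of these differences can be set against a spread between repeats.

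The response of Ri17 minus that of Col-0 asked whether the line answered the treatments differently, without a test. *CHS*, the chalcone synthase gene, had a response of -6.19 in Ri17 and -2.71 in Col-0 at 1 h of MeJA, and of -5.15 and -1.06 at 30 min of wounding, after standing 2.78 higher in untreated Ri17. *AT2G44240* had the highest response difference at 30 min of wounding, 7.08, and *AT5G20790* at 60 min, 7.63. The early wound list responded more in Ri17 at 60 min (median 1.08, percentile 100, 4 of 12 genes under the floor on 1 or both untreated arrays) and salicylate defence at 30 min (median 1.25, percentile 99.98). The early wound value contains the untreated pair, in which that list stood lower in Ri17. Response differences of at least 1 numbered 1634 at 1 h of MeJA, 2059 at 4 h, 2274 at 30 min and 2882 at 60 min of wounding. These counts were made among the 15382 kept probe sets without a rule on the Present call, unlike the counts of genotype differences.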

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

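The contrasts between times, the tests of explanations and the splits of the arrays in this part were chosen only after the results they concern had been seen.

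Among listed genes, 3 had opposite effects at 1 h and 4 h of MeJA, and the difference between the times was itself tested. *VQ10*, of the VQ motif family, lay under the floor on both arrays at 1 h, so that its -1.62 there and the difference of 2.78 to its 1.15 at 4 h (adjusted p = 0.00531) are bounds. *TCH2*, a calmodulin-like touch gene, measured 1.88 and then -1.28, a difference of -3.16 (adjusted p = 0.0019). *COR47*, a dehydrin gene, measured 1.02 and then -0.85, a difference of -1.88 (adjusted p = 0.00401). The effects at single times were less firm. The calls at 4 h were lost for *VQ10* without any of 7 arrays (0.74 without the untreated Ri17 array, adjusted p = 0.232), for *TCH2* without any of 3 (-0.95 without the untreated Col-0 array, adjusted p = 0.0597) and for *COR47* without any of 3 (-0.71 without the untreated Ri17 array, adjusted p = 0.101). Those at 1 h were lost for *VQ10* without any of 3 (a floored -1.20 without the untreated Col-0 array, adjusted p = 0.0924) and for *COR47* without the Col-0 array at 1 h (0.74, adjusted p = 0.0988) or the untreated Col-0 array (0.88, adjusted p = 0.0687).

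Other genes had responses of opposite sign in Col-0 and Ri17, each from single arrays, and these differences were not tested. Under MeJA at 1 h the response of Ri17 minus that of Col-0 was 2.52 for *AT1G26930*. At 4 h it was at least 2.15 for *PDF1.2B*, a defensin gene under the floor on the treated Col-0 array, 3.12 for *AT4G16260*, a glucanase gene, 2.83 for *AT2G37750*, -3.55 for *AT5G01015* and -3.54 for *STOMAGEN*. At 30 min of wounding it was 7.08 for *AT2G44240*, 4.34 for *AT5G55450*, 3.71 for *AT3G49340*, -6.08 for *AT5G48490*, -4.57 for *AT1G11850* and -3.96 for *STOMAGEN*. At 60 min it was 7.63 for *AT5G20790*, 6.78 for *AT2G44240*, 6.71 for *AT5G39520*, 4.94 for *AT1G19200* and 4.82 for *AT2G37750*. At the same time it was -5.85 for *AT1G11850*, -5.32 for *AT5G48490*, -4.55 for *AT2G10940* and -4.20 for *AT1G13650*.

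*PR2* fell at 1 h of MeJA, as did 54 of 147 probe sets described as disease resistance, while 11 of these rose and 82 did not pass (adjusted p = 0.343 for the group with an estimated correlation). A full stop of synthesis followed by decay at 1 rate would have carried 23 members that had fallen by 1 h, and were still above double the floor, down by a median of 2.36 more by 4 h. Their median change was -0.0050, but 32 of the 55 fallen members, *PR2* among them, lay too near the floor to show further decay, so that course stays open. Other scalings left the median at 1 h at -0.50 or lower, which argues against scaling as the whole cause. Another run for the MeJA arrays is a candidate explanation: 23 of 45 bacterial control probe sets separated the MeJA arrays from the others, where chance gives 0.952% for each. They comprised 17 of 27 poly-A and 6 of 18 hybridization controls, and several measure the same transcript. Added controls cannot show whether the plants differed, so another set of plants was not tested. Either would coincide with the treatment, so neither can be told apart from the hormone, and they may hold together. Another tissue was not tested and stays open, since the design speaks of seedlings for MeJA and of leaves otherwise. The vascular gene *SUC2* also fell at 1 h (-1.29). Root genes cannot decide the tissue, since only 3 of 10 listed had a probe set and 1 was kept. That gene, *NRT2.1*, fell (-1.67 or lower), and *EXP7* and *EXP18* were called Present on 0 arrays. A fall in response to MeJA, or to the medium or handling that went with it, stays open as the biological explanation. Even with synthesis fully stopped at the start, *PR2* mRNA would have to halve every 7.68 min or faster to reach its 1 h level.

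*CCA1* stood lower after each treatment, and *TOC1* and *GI* higher after wounding. If time since 1 common untreated harvest were the source, equal times would give equal falls, yet *CCA1* differed by -2.82 ± 0.23 between 60 min of wounding and 60 min of MeJA. The fall at 60 min of wounding was still -5.13 under the scaling that shrank it most, which argues against scaling. The falls after wounding use no MeJA array, so a separate handling of those arrays, if there was one, stays open for the falls under MeJA alone. Different hours of harvest or a clock response to wounding could each account for the falls after wounding and were not tested. With synthesis fully stopped, the *CCA1* mRNA would have to halve every 8.02 min to show its fall at 30 min of wounding. The hour of harvest was not tested for other falls after wounding either, such as that of *F3H*.

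Response differences between the genotypes correlated across probe sets between treatments, with r from 0.61 to 0.77. The pair of untreated arrays, which every response difference contains, made up at least 65.5% of the covariance in each of 6 pairs of treatments, so that this shared pair is a candidate explanation for most of the likeness. At least 86.0% of response differences of 1 or more kept that size after quantile normalisation, which argues against scaling. Between treated conditions, which share no array, the genotype differences correlated with r = 0.33 for the 2 wounding times, the highest of 6 pairs, and from -0.01 to 0.19 for the others. The difference in the untreated pair correlated with those of the 4 treated conditions with r from -0.20 to 0.01, so it gave no sign of a genotype difference shared with treated plants. Whether it came from genotype in untreated plants or from a single unusual array stays open.

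For the genotype effect the real count was 0 and the highest of the other splits of the 10 arrays into 5 and 5 gave 20. All 100 of 100 splits must give at least 0, so this count says nothing about chance. The splits that gave 20 parted the arrays of 1 condition, where the real one parts those of all 5, and the 15 other splits that part all 5 gave 0. At an unadjusted p under 0.05 the real split gave 951 probe sets and the highest of those 15 gave 1889, and 16 such splits are too few for a share under 0.05. In simulated data, 95 of 100 genes changed by 2 on the log2 scale between the genotypes were called. Those changes were equal in all 5 conditions, in genes with higher mean signal. The simulation therefore does not show whether differences confined to some conditions would be called.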

How the results depend on the processing

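Leaving out 1 array at a time gave totals of 2467 to 4911 at 1 h of MeJA, 3149 to 5828 at 4 h, 1452 to 3143 at 30 min of wounding and 2781 to 3922 at 60 min, the low values coming from fits without an array of the treatment itself, where the treated level rests on 1 array. In a fit on wounded and untreated arrays alone, chosen after seeing the data, the totals were 1467 at 30 min and 2628 at 60 min, with fewer residual arrays. The genotype count stayed at 0 under every alternative run. Of the 19 list results called, camera with an estimated correlation kept 0, fry 18 (28 calls in all) and quantile normalisation 19 (21 in all). For Ri17 against Col-0 on single arrays, the authors' change calls, which need no 2-fold size, numbered 4209 untreated, 1530 and 2049 under MeJA at 1 h and 4 h, and 2673 and 4322 at 30 and 60 min of wounding. A double floor gave 81 and 139 under MeJA at 1 h and 4 h, and a Present call on both arrays gave 101 at 1 h of MeJA and 446 at 30 min of wounding, the cause of which was not tested. Single genes and lists gave 10164 unchanged outcomes, 383 that lost their call, 124 that gained one and 27 that moved, with 0 reversed among the named genes. Unchanged outcomes include genes that were never called. Alternatives other than leaving out 1 array lost the call for 16 of 70 called named genes at 1 h of MeJA and 13 of 75 at 4 h. At 30 and 60 min of wounding they lost it for 18 of 66 and 11 of 70. Signal over background limits what the arrays show, since 26.8% to 32.5% of probe sets lay at or below the floor. Signals of the comparison tables equal those of the series table, so that alternative was not run.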

Other observations

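No test in this part was chosen after its result was seen, but which groups to print was. The groups were defined from words in the deposited descriptions. Genes of ethylene-responsive element binding proteins rose in 15 of 25 cases at 1 h of MeJA (list adjusted p = 3.43e-05, adjusted p = 0.257 with an estimated correlation) and in 17 of 25 at 30 min of wounding (list adjusted p = 1.43e-10, adjusted p = 0.157 with an estimated correlation). Myrosinase and jacalin-like lectin genes, parts of a chemical defence, rose in 12 of 19 cases at 4 h of MeJA (list adjusted p = 2.91e-04, adjusted p = 0.343 with an estimated correlation). Of 290 ribosomal protein probe sets 124 rose and 13 fell at 4 h of MeJA (list adjusted p = 2.70e-08, adjusted p = 0.682 with an estimated correlation). Of 147 disease resistance probe sets 54 fell and 11 rose at 1 h of MeJA (list adjusted p = 9.65e-05, adjusted p = 0.343 with an estimated correlation). WRKY factor genes rose in 11 of 26 cases at 60 min of wounding (list adjusted p = 5.98e-05, adjusted p = 0.444 with an estimated correlation).

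In untreated Ri17 against untreated Col-0, ribosomal protein genes were higher in 263 of 290 cases (median 0.47) and expansin genes, which loosen cell walls, in 13 of 15 (median 1.09), both above 100% of random lists. NAC factor genes had a median of -0.36. At 60 min of wounding, expansin genes lay lower in Ri17 (median -0.71 or lower), as did xyloglucan endotransglycosylase genes (median -0.54 or lower), the genes that set these medians being under the floor, while WRKY genes (0.60), NAC genes (0.43) and chitinase genes (0.79) lay higher. These are differences between single arrays, and the random lists do not allow for genes that move together.

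Several lists were small. Among marker genes, the phloem transporter gene *SUC2* fell by 1.29 and 1.53 under MeJA at 1 h and 4 h, and of 4 vascular genes 2 fell at each time (3 and 4 adjusted over the list alone), the call for *XCP1* at 1 h being lost without the Col-0 (-1.27) or Ri17 array (-1.17) of that time. The 1 root gene kept, *NRT2.1*, fell at both, to -1.67 or lower, with all 4 MeJA arrays under the floor. *EXP7* and *EXP18* also had a probe set and were called Present on 0 arrays. Of 3 epidermis and guard cell genes 1 fell at 4 h, *KAT1* by 0.85 (0 adjusted over the list alone, and lost without any of 7 arrays, -0.60 without the untreated Col-0 array, adjusted p = 0.224), and none of the 2 flower genes passed in any treatment. No seed gene was kept. The indole glucosinolate list had 1 of 2 genes higher at 60 min of wounding, *MYB34* by 1.61. Photosynthesis genes stayed mostly unchanged, with 1 of 6 lower at 4 h of MeJA, *GAPA* by 0.91, a call lost without the Col-0 array (-0.94, adjusted p = 0.0618) or the Ri17 array (-0.88, adjusted p = 0.0713) of that time.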
